A study of Homo sapiens with 9 samples.

How the data were processed

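CUT&RUN libraries of DND-41 cells were prepared with protein A/G-micrococcal nuclease and sequenced as paired ends, per the labels' protocols. The series has 9 samples, of which 5 had a peak list: H3K4me3, BRG1, RUNX1, and H3K27ac after 100 nM ACBI-1 or DMSO. The remaining 4 are IgG or input controls and were not analysed here. Samples were grouped by the antibody and treatment in their titles, which left 1 library per group.

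The authors deposited each list as 4 columns with chromosome, start, end and peak name. No score, fold, p-value or read count accompanies a peak, so the values used are positions, with no unit of signal and no normalization. The build is hg19 and the callers named are MACS2 and SEACR, per the submitters' processing notes. Per the file headers, the RUNX1 list holds MACS2 peaks, and both H3K27ac lists hold broad peaks from a CUT&RUN pipeline at q below 0.01. The thresholds of the BRG1, H3K4me3 and RUNX1 lists, the aligner, the handling of duplicates for most lists, the use of controls in peak calling and any pooling of replicates are not given in the sources used here. The lists came from more than 1 set of settings, so the numbers of peaks of different targets are not comparable. The H3K27ac lists share their stated settings. The headers also name a spike-in scaled signal track, which was not used here. A peak list depends on depth and on enrichment over background: a library with fewer reads or more background gives fewer and narrower peaks. With the depth unknown, no interval below covers that.

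Overlaps were computed from these positions in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Peaks were shared when they overlapped by at least 1 bp. The overlap counts and covered lengths were checked against bedtools 2.31.1 for the 25 ordered pairs of lists, with 0 peaks differing. Shares carry exact Clopper-Pearson 95% intervals over peaks. Neighbouring peaks are not independent, so differences between classes carry intervals from 1000 resamples of 5 Mb blocks of the genome. As a reference for each overlap, the second list was placed at random on the same chromosomes 100 times. Positions ran from the start of the chromosome to the end of its last peak. Unmappable gaps were not excluded, which lowers the random overlap. None of these intervals measures the spread between cultures.

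A DMSO H3K27ac peak was called lost when no ACBI peak overlapped it, and an ACBI peak gained when no DMSO peak overlapped it. Shares lost were standardised for width in 10 bins of about equal size, weighted by all DMSO peaks. On losses simulated on the DMSO peaks without a class effect, the crude difference by H3K4me3 was -19.7 percentage points and the standardised one 0.415. With a simulated effect of -15 points the standardised difference was -14.7. The simulated loss changed with width only between these same 10 bins. It therefore checks the computation and cannot show whether width differences within a bin matter. Those were examined only by using 50 bins in place of 10. That was done for both factors minus neither and for the comparison by H3K4me3, not for the factor classes split by H3K4me3.

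The overlap shares, the shares lost and gained, the shares lost by factor and by H3K4me3, the gene lists, the rule for named sites and some alternatives were fixed before the data were examined. The standardisation by factor was fixed on peak width and strength and was done on width alone, since the lists hold no strength. For the comparison by H3K4me3 only the crude shares were fixed then, and its standardisation for width was added after seeing the data. Also added then were the block intervals, the count of both factors among H3K27ac peaks of like width, the factor classes split by H3K4me3, the shares at RUNX1 peaks, the widths of paired and broad peaks, the gained peaks by class and the 5 Mb bins. Width also replaced strength in the rule for named sites, which takes the 10 co-occupied sites with the lowest sum of width ranks and the 10 widest lost and gained peaks. Without an annotation of hg19, no peak was assigned to a gene, and the fixed lists of leukemia, NOTCH1 pathway, T-cell, SWI/SNF, cell cycle, housekeeping and other lineage genes were not tested. The gene table given is for GRCh38 and its coordinates were not used. Promoter sites were taken from H3K4me3 alone. The alternatives chosen then were other overlap rules, the autosomes and X only, merged H3K27ac peaks and a minimum width of 500 bp. Alternatives by width, by the standard used and by a minimum of 20 peaks per width bin were added after seeing the data.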

Results

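Chromatin of DND-41, a cell line derived from a human T-cell acute lymphoblastic leukemia, was profiled by CUT&RUN. In this assay an antibody tethers a fusion of protein A/G and micrococcal nuclease to its target, and the DNA that the enzyme releases is sequenced. The targets were BRG1 (the SMARCA4 ATPase of the SWI/SNF chromatin remodeling complexes), RUNX1 (a sequence-specific transcription factor of the hematopoietic lineages), H3K4me3 (a histone mark found mainly at active promoters) and H3K27ac (a mark of active promoters and enhancers). BRG1, RUNX1 and H3K4me3 carried no treatment label. H3K27ac was profiled after 100 nM ACBI-1, a degrader of the SWI/SNF ATPases and PBRM1, and after its vehicle, DMSO. Peak lists of 5 libraries were analysed, with 1 library per target and condition, so no difference below has a replicate check and no p-value is given. The 4 control libraries of the series (IgG or input) were not analysed here. By its title the control for RUNX1 is an input, while the other controls are IgG. The RUNX1 library may therefore have been made differently from the others.

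The lists held 7445 BRG1 peaks, 19893 RUNX1 peaks, 12834 H3K4me3 peaks, 90495 H3K27ac peaks in DMSO and 52967 H3K27ac peaks in ACBI. BRG1 peaks had a median width of 284 bp and covered 2.36 Mb. RUNX1 peaks had a median width of 402 bp and covered 9.58 Mb. H3K4me3 peaks had a median width of 1420 bp and covered 19.4 Mb. Read depth is unknown, since the lists hold positions only. Intervals on shares of peaks are exact Clopper-Pearson 95% intervals, which cover counting error only. Coordinates are in hg19 and count from 1. They are given without gene names, since no annotation of that build was used here.

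The first comparison asked where BRG1 and RUNX1 meet in the cells without a treatment label. Most BRG1 sites were also RUNX1 sites: 6006 of the 7445 BRG1 peaks (80.7%, 95% interval 79.8 to 81.6) overlapped a RUNX1 peak by at least 1 bp. Of the 19893 RUNX1 peaks, 5920 (29.8%, 29.1 to 30.4) overlapped a BRG1 peak. The midpoints of overlapping BRG1 and RUNX1 peaks were a median of 71.5 bp apart, and 4035 BRG1 peaks lay wholly inside RUNX1 peaks. When the RUNX1 peaks were placed at random on their chromosomes 100 times, a mean of 0.582% of BRG1 peaks were overlapped, and 0.940% at most. With BRG1 peaks placed at random, 0.219% of RUNX1 peaks were overlapped on average, and 0.317% at most.

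Random placement ignores that both factors sit in active chromatin, so the pair was also counted inside H3K27ac peaks. Among the DMSO H3K27ac peaks, 6217 held BRG1, 13067 held RUNX1 and 5260 held both. Independent placement among peaks of like width would give 1915 with both, and independent placement among peaks of like width and H3K4me3 status would give 3287. The observed number was 2.75 and 1.60 times these values. Like width here means the same of 10 width bins. The widest bin ran from 3015 to 116256 bp and held 1912 of the 5260 peaks, so width differences within it may raise both ratios. The shares depended on how overlap was counted: the share of RUNX1 peaks with BRG1 was 16.6% when 50% of the peak had to be covered. With equal numbers of the widest peaks of each list it was 45.2%, and the share of BRG1 peaks with RUNX1 was 47.3%.

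The factor sites were then set beside the histone marks. Of the BRG1 peaks, 61.8% (60.7 to 62.9) overlapped H3K4me3 and 91.9% (91.3 to 92.5) overlapped H3K27ac in DMSO. Of the RUNX1 peaks, 43.0% (42.4 to 43.7) overlapped H3K4me3 and 83.8% (83.3 to 84.3) overlapped H3K27ac in DMSO. Random placement of the mark gave 0.881% and 5.60% for BRG1, and 0.988% and 6.19% for RUNX1. RUNX1 peaks with BRG1 were on H3K4me3 in 63.6% of cases (62.4 to 64.9), against 34.3% (33.5 to 35.1) of RUNX1 peaks without BRG1. They were also wider, with a median of 531 bp against 350 bp. BRG1 peaks differed less by their partner: 62.4% (61.1 to 63.6) of those with RUNX1 and 59.3% (56.8 to 61.9) of those without it were on H3K4me3. With equal numbers of the widest peaks, the shares on DMSO H3K27ac were 29.2% for BRG1 and 55.5% for RUNX1, since this setting keeps only the widest H3K27ac peaks.

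**Figure D1:**
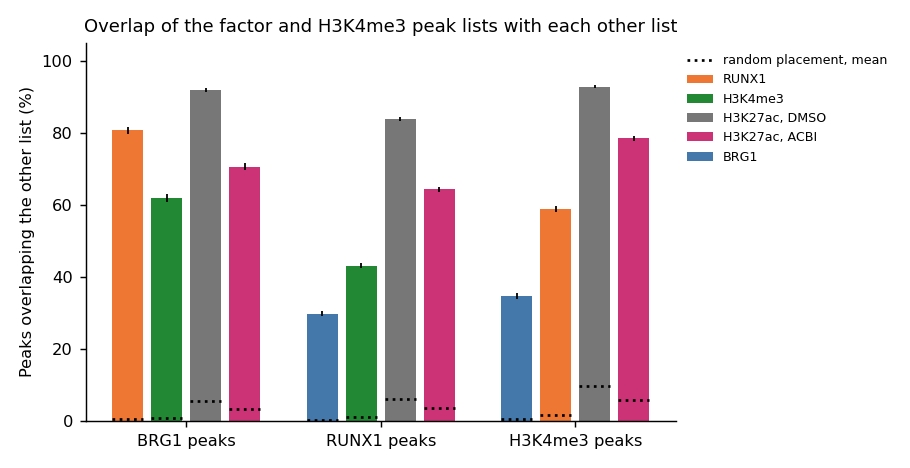
Bars give the percentage of BRG1, RUNX1 and H3K4me3 peaks that overlap each other list by at least 1 bp, with exact 95% intervals, and dotted lines give the mean of 100 random placements of the other list. BRG1 peaks overlap RUNX1 in 80.7% of cases, RUNX1 peaks overlap BRG1 in 29.8%, and each of the 3 lists overlaps H3K27ac less in the ACBI library than in the DMSO library.

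The 10 co-occupied sites that ranked highest by the widths of both peaks all lay in DMSO H3K27ac, 6 of them on H3K4me3, and 9 still overlapped an H3K27ac peak in ACBI. The first was on chromosome 8, where a BRG1 peak of 1157 bp (101964096 to 101965252) lay inside a RUNX1 peak of 3265 bp (101962538 to 101965802), and H3K4me3 and both H3K27ac lists covered it fully. The second was on chromosome 7 (114649138 to 114650193) and the third on chromosome 9 (20209434 to 20210451). Both lay off H3K4me3, and H3K27ac covered them fully in both conditions. The exception was on chromosome 14 (105956881 to 105957725), where DMSO H3K27ac covered 211 bp of the 845 bp BRG1 peak and ACBI H3K27ac covered none. At a site on chromosome 15 (31618460 to 31619582), the H3K27ac cover of the BRG1 peak was 1123 bp in DMSO and 148 bp in ACBI. The others were at 153237305 to 153238323 on chromosome X, 14647048 to 14648011 on chromosome 1, 35884491 to 35885311 on chromosome 5, 30709592 to 30710605 on chromosome 16 and 17783421 to 17784568 on chromosome 3.

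The second comparison asked how the H3K27ac landscape differed after the SWI/SNF degrader. The ACBI library had 41.5% fewer peaks than the DMSO library, and they covered 70.8 Mb against 127.2 Mb. Of the DMSO peaks, 53490 (59.1%, 58.8 to 59.4) had no overlapping ACBI peak and are called lost here. Of the ACBI peaks, 11324 (21.4%, 21.0 to 21.7) had no overlapping DMSO peak and are called gained. The balance depends on the lengths of the lists: with equal numbers of the widest peaks, 40.7% were lost and 30.4% gained. Lost peaks were narrow, with a median width of 499 bp against 1642 bp for kept peaks, and gained peaks were narrow too, with a median of 378 bp. Lost peaks held 34.9 Mb and gained peaks 5.41 Mb. A lost peak is one that the caller did not report in the ACBI library, which does not show that the mark was absent.

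Kept peaks were mostly called narrower in ACBI, which a library of lower depth could also give. In 28543 pairs of exactly 1 DMSO and 1 ACBI peak, the median width was 1457 bp in DMSO and 880 bp in ACBI, and the ACBI peak was the narrower in 74.5% of pairs. A further 5100 DMSO peaks were overlapped by several ACBI peaks each. Broad domains were kept in part. None of the 970 DMSO peaks of 10 kb or more was lost, and ACBI peaks covered 79.2% of their length. Taking 3 counts as the limit for a count of 0, in place of an exact interval, a share of up to 0.309% is allowed. Since 1 bp of overlap counts as kept, so wide a peak is seldom called lost, and the count of 0 says little by itself. The ACBI list held 494 peaks of that size. The widest DMSO peak, on chromosome 17 (55476001 to 55592256), was covered over its whole 116256 bp by an ACBI peak of 187633 bp (55471874 to 55659506). The gained share depended on how near a peak had to be: 12.4% of ACBI peaks counted as gained when a DMSO peak within 1 kb was accepted and 32.4% when 50% of the peak had to be covered.

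The share lost was next compared between DMSO peaks with and without H3K4me3. Peaks that overlapped H3K4me3 were lost in 14.5% of cases (13.8 to 15.2; 1536 of 10598), and peaks away from it in 65.0% (64.7 to 65.4; 51954 of 79897). Promoter-marked peaks were wider, with a median of 1845 bp against 659 bp, and width went with retention: of 10 width bins of about equal size, 91.0% of the DMSO peaks in the narrowest (158 to 211 bp) and 4.04% of those in the widest (3015 bp or more) were lost. The rule of 1 bp overlap itself makes a wide peak more likely to count as kept. Standardised to the same widths, an adjustment chosen after seeing the data, 41.1% of peaks with H3K4me3 and 61.8% of peaks without it were lost. The difference was 20.7 percentage points (19.2 to 22.3, from resampling 5 Mb blocks of the genome). Peak strength was not used here, so peaks of like width can still differ in height.

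DMSO peaks that held a factor were lost less often than peaks that held none. Peaks with both BRG1 and RUNX1 were lost in 13.9% of cases (13.0 to 14.9; n = 5260 peaks), those with BRG1 alone in 19.96% (17.5 to 22.6; n = 957), those with RUNX1 alone in 25.04% (24.1 to 26.0; n = 7807) and those with neither in 66.2% (65.8 to 66.5; n = 76471). At the same widths the classes were closer, at 50.9%, 42.5%, 51.8% and 61.2%. Peaks with both factors were then lost less often than peaks with neither by 10.3 percentage points (interval of the difference -12.4 to -8.25), and the difference between peaks with both factors and peaks with RUNX1 alone was -0.840 points (-3.16 to 1.46). Counting an ACBI peak within 1 kb as kept brought the difference between both factors and neither to -3.36 points (-5.50 to -1.0). It was -18.7 points with equal numbers of the widest DMSO and ACBI peaks and -16.2 points with H3K27ac peaks of at least 500 bp only. The difference also turned with H3K4me3: at the same widths it was 6.53 points (3.21 to 9.44) on H3K4me3 and -4.64 points (-7.74 to -1.52) away from it. The pooled -10.3 points lie outside both values, so they are not a measure of the factors alone. Of the 5260 peaks with both factors 3545 were on H3K4me3, against 3032 of the 76471 peaks with neither.

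**Figure D2:**
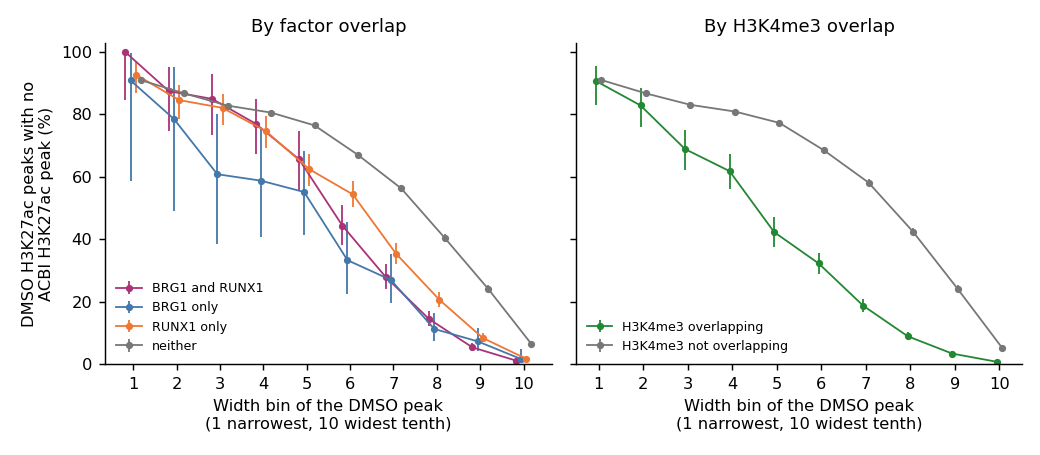
Percentage of DMSO H3K27ac peaks with no overlapping ACBI peak, in 10 bins of DMSO peak width, by overlap with BRG1 and RUNX1 (left) and with H3K4me3 (right). Bars are exact 95% intervals over peaks. The share lost goes from 91.0% in the narrowest bin to 4.04% in the widest over all peaks, and from the middle widths on it is highest for peaks without a factor or without H3K4me3.

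The difference by factor was not the same with and without H3K4me3. Away from H3K4me3, peaks with both factors were lost in 17.8% of cases (16.1 to 19.7; n = 1715), those with RUNX1 alone in 37.0% (35.6 to 38.4; n = 4410) and those with neither in 68.0% (67.7 to 68.3; n = 73439). On H3K4me3, the corresponding shares were 12.02% (10.96 to 13.1; n = 3545), 9.54% (8.57 to 10.6; n = 3397) and 22.5% (21.0 to 24.0; n = 3032). Peaks with BRG1 alone were lost in 16.8% of cases on H3K4me3 (13.97 to 19.998; n = 624) and in 25.8% away from it (21.2 to 30.9; n = 333). At the same widths the order on H3K4me3 changed: 47.7% of peaks with both factors, 35.96% of peaks with RUNX1 alone and 41.1% of peaks with neither were lost, beside 43.7% (36.1 to 47.97) of peaks with BRG1 alone. Away from H3K4me3, 45.7% (39.4 to 51.9) of peaks with BRG1 alone and 57.7% (54.7 to 60.6) of peaks with both were lost at the same widths. The values for BRG1 alone rest on few narrow peaks: before the split by H3K4me3, width bins 1 and 2 held 11 and 14 of them. No minimum per bin was applied to them, and a bin without peaks of a class was left out of its share. On H3K4me3, peaks with both factors were lost more often than peaks with RUNX1 alone at the same widths, by 11.7 points (7.45 to 16.0), while the difference away from H3K4me3 was -3.11 points (-6.35 to 0.340). Without the narrowest width bin, which held under 20 peaks of a class, the latter was -4.15 points (-7.77 to -0.284). The sizes depended on the widths used as the standard. With the widths of peaks that overlap a factor, both factors minus RUNX1 alone came to 5.41 points on H3K4me3 and -5.01 points (-7.23 to -2.59) away from it, and both factors minus neither to 2.80 and -9.92 points. Weighted to the widths of the peaks with RUNX1, the difference by BRG1 was 5.30 points on H3K4me3 and -4.79 points away from it, and these differed by 10.1 points (7.25 to 12.8). The shares were also counted at the RUNX1 peaks themselves. Of the RUNX1 peaks on H3K4me3 that lay in DMSO H3K27ac, 77.4% (76.0 to 78.8) of those with BRG1 and 86.1% (85.0 to 87.1) of those without it still overlapped H3K27ac in ACBI. Away from H3K4me3, the shares were 81.9% (80.1 to 83.6) with BRG1 and 66.7% (65.5 to 67.8) without it.

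**Figure D3:**
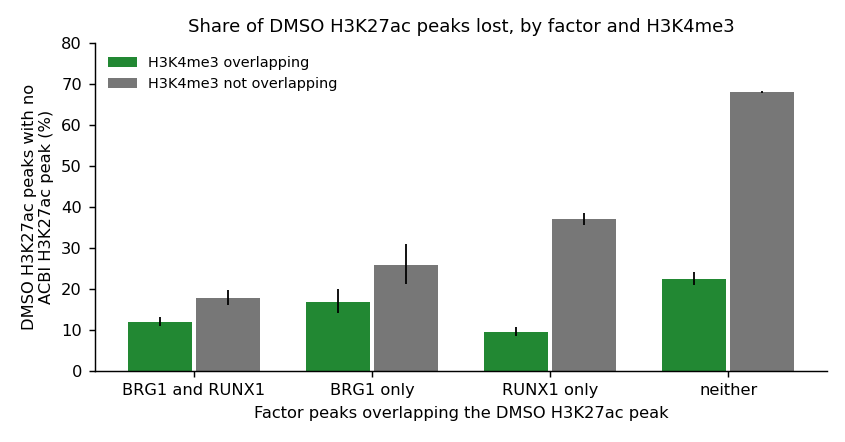
Percentage of DMSO H3K27ac peaks with no overlapping ACBI peak, not adjusted for width, for 4 classes of factor overlap, with H3K4me3 (green) and without it (grey). Error bars are exact 95% intervals over peaks. Peaks with neither factor and no H3K4me3 have the highest share, 68.0%, and peaks with RUNX1 alone on H3K4me3 the lowest, 9.54%.

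Gained peaks lay by definition outside DMSO H3K27ac, which already held 91.9% of the BRG1 peaks, 83.8% of the RUNX1 peaks and 92.8% of the H3K4me3 peaks. Low overlap with these lists is therefore largely set by the definition. Of the ACBI peaks that overlapped BRG1 or RUNX1, 78 of 10856 were gained (0.718%, 0.568 to 0.896), and of those on H3K4me3, 84 of 9458 (0.888%, 0.709 to 1.10). Of the ACBI peaks with none of the 3, 11170 of 38940 were gained (28.7%, 28.2 to 29.1). These classes differ in width too, with medians of 1605 bp for peaks with a factor and 612 bp for peaks with none of the 3. The factor and H3K4me3 libraries carried no treatment label, so sites bound only after ACBI may not be counted.

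The 10 widest lost peaks measured 5999 to 9858 bp. None overlapped H3K4me3 or BRG1, and 3 overlapped RUNX1. The widest was on chromosome 11 (32448882 to 32458739), with the nearest ACBI peak 3344 bp away. The second was also on chromosome 11 (121422214 to 121429731) and held 457 bp of RUNX1 peak. The third was on chromosome 3 (14951517 to 14958676). A peak of 6092 bp on chromosome 11 (2321660 to 2327751) was the most isolated, with the nearest ACBI peak 30781 bp away. At the opposite end, a lost peak of 6212 bp on chromosome 20 (45894358 to 45900569) lay 34 bp from an ACBI peak. The others were at 23291693 to 23298450 and 35815004 to 35821096 on chromosome 22, 665874 to 672409 on chromosome 16, 131055673 to 131062178 on chromosome 12 and 143354883 to 143360881 on chromosome 8.

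The 10 widest gained peaks measured 2495 to 3642 bp, and none overlapped H3K4me3, BRG1 or RUNX1. The widest was on chromosome 14 (99650196 to 99653837), 1201 bp from the nearest DMSO peak. The second, on chromosome 4 (130283839 to 130287323), was 9107 bp from one, the largest distance among the 10. The third, on chromosome 1 (5994240 to 5997180), was only 125 bp from one. The others were at 112851418 to 112854352 on chromosome 9, 74457391 to 74460319 on chromosome 4, 19422490 to 19425334 on chromosome 22, 905477 to 908301 on chromosome 5, 86315564 to 86318299 on chromosome 2, 23492138 to 23494751 on chromosome 21 and 80496511 to 80499005 on chromosome 17.

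**Figure D4:**
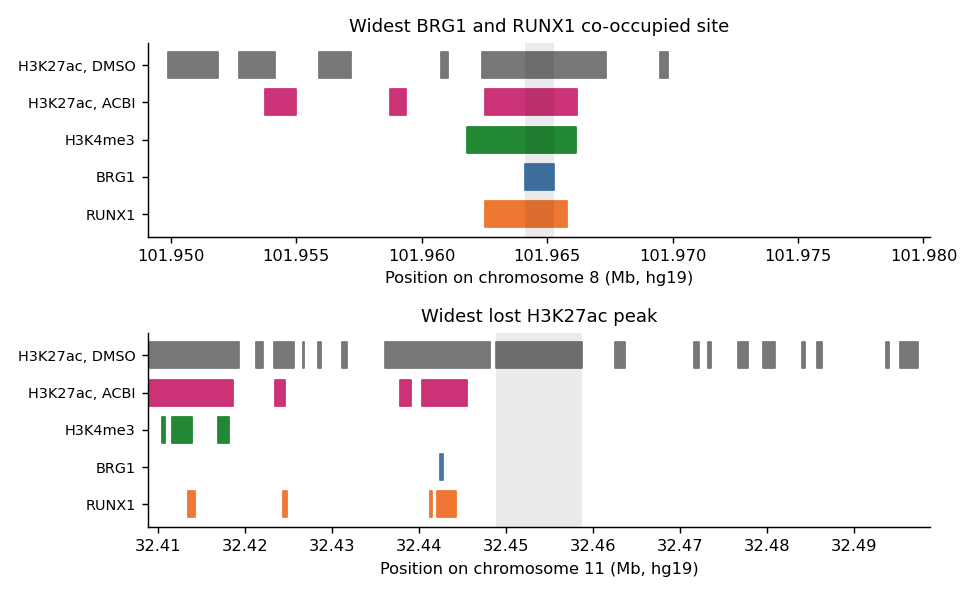
Peaks of the 5 lists around the highest-ranked co-occupied site (chromosome 8, top) and the widest lost H3K27ac peak (chromosome 11, bottom), drawn to scale in Mb, with the named BRG1 peak and the named lost peak shaded. The lost peak measures 9858 bp and the nearest ACBI peak lies 3344 bp from it.

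Along the genome, H3K27ac covered less length in ACBI on each of the autosomes and X, with ratios of ACBI to DMSO between 0.485 on chromosome 8 and 0.702 on chromosome 20. The ratio over all sequences was 0.556. In 5 Mb bins with at least 50 kb of DMSO H3K27ac, the median log2 ratio was -0.93 (quartiles -1.12 and -0.71, n = 487 bins), and 3 bins had more covered length in ACBI than in DMSO.

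**Figure D5:**
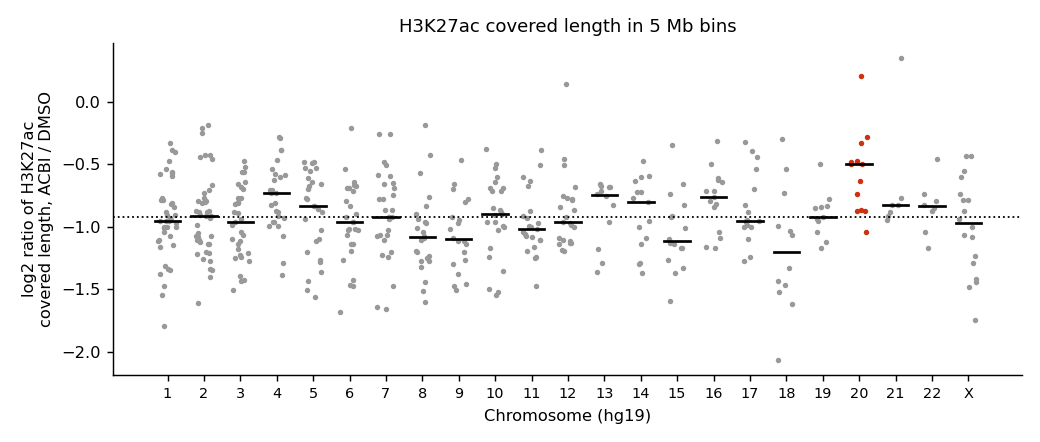
Log2 ratio of H3K27ac covered length, ACBI over DMSO, in 5 Mb bins (points) by chromosome, with the median per chromosome (black lines) and over all bins (dotted line, -0.93). Chromosome 20 (red) has the highest median, -0.50.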

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

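The settings by peak width rank, the 50 width bins, the other width standards and the minimum of 20 peaks per width bin were chosen only after the result was seen. The width-standardised differences in share lost kept their direction under the alternatives given here. The crude difference does not always share it: on H3K4me3, both factors minus neither was -10.4 points crude and 6.53 points standardised. Over all results, 18 values stayed within the interval of the reported one and 56 moved out of it. The values for the autosomes and X only and for 50 width bins were among the 18. With 50% of the peak covered, the shares were 16.6% (RUNX1 on BRG1), 76.1% (BRG1 on RUNX1), 58.8% and 88.9% (BRG1 on H3K4me3 and on DMSO H3K27ac), 40.1% and 79.7% (RUNX1 on the same marks), 75.6% (DMSO peaks lost) and 32.4% (ACBI peaks gained). The standardised differences were -13.6 points (both factors minus neither, not split by H3K4me3) and 25.4 points (without minus with H3K4me3). With peaks within 1 kb counted as shared, the same quantities were 34.8%, 83.4%, 63.8%, 94.9%, 45.4%, 87.1%, 51.0% and 12.4%, and -3.36 and 16.0 points. With the wider 50% of each list, they were 24.3%, 66.0%, 47.4%, 89.0%, 32.2%, 82.8%, 53.6% and 14.3%, and -13.1 and 26.5 points. With equal numbers of the widest peaks, they were 45.2%, 47.3%, 46.6%, 29.2%, 45.6%, 55.5%, 40.7% and 30.4%, and -18.7 and 28.0 points. Merging H3K27ac peaks within 1 kb gave 58.0% lost, 20.9% gained, -14.5 and 23.9 points. Keeping H3K27ac peaks of at least 500 bp gave 55.2% lost, 17.1% gained, -16.2 and 26.2 points. Standardising to the widths of the overlapping peaks gave -15.0 and 22.9 points. For the classes split by H3K4me3, the widths of peaks that overlap a factor gave 2.80 points (both factors minus neither) and 5.41 points (both minus RUNX1 alone) on H3K4me3, and -9.92 points (both minus neither) away from it. Leaving out also the width bin with under 20 peaks gave 2.72, 5.29 and -10.1 points. For the differences, these overlap rules were applied to the ACBI peaks only, since factor peaks are narrower than most H3K27ac peaks. The intended rankings by p and the gene windows were not run, since the lists hold no p and no annotation of the build was used. No paired analysis was possible because each condition has 1 library, so leaving out a replicate was not possible either. Depth is unknown, which limits the comparison of peak numbers between the ACBI and DMSO libraries.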

Other observations

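The tests of peak width for the first and second patterns below, of depth, of long domains and of H3K4me3 peaks by BRG1 were chosen only after the result was seen. The change in H3K27ac covered length was uneven along the chromosomes. The lowest ratio was in a 5 Mb bin on chromosome 18 (25000001 to 30000000), with 23.9 kb in ACBI against 99.98 kb in DMSO. Next came bins on chromosome 1 (220000001 to 225000000), with 45.4 kb against 157 kb, and chromosome X (145000001 to 150000000), with 29.5 kb against 98.8 kb. The 3 bins with more length in ACBI were on chromosome 21 (20000001 to 25000000), with 77.3 kb against 60.7 kb, chromosome 20 (10000001 to 15000000), with 329 kb against 285 kb, and chromosome 12 (30000001 to 35000000), with 133 kb against 121 kb. These bins were picked for their values, and each has 1 library per condition.

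The first pattern is that DMSO H3K27ac peaks away from H3K4me3 were lost more often than those on it. The values argue against peak width as the whole cause, since the crude gap of 50.5 points was still 20.7 points (19.2 to 22.3) at the same widths. A lower depth or weaker enrichment in the ACBI library stays open, and an effect of the degrader itself was not tested apart from it. In the one-to-one pairs 25.4% of peaks were wider in ACBI, which neither excludes nor shows a shallower library, because read counts are not in the lists. If promoter peaks are taller than other peaks of like width, lower depth alone could give this pattern. The pattern is one of DMSO peaks and was reversed, without adjustment for width, when counted at BRG1 peaks in DMSO H3K27ac. Of these, 74.4% (73.1 to 75.7) on H3K4me3 and 79.7% (78.0 to 81.3) away from it still overlapped H3K27ac in ACBI. The same shares of RUNX1 peaks were 82.2% and 70.1%.

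The second pattern is that BRG1 went with more loss of H3K27ac at RUNX1-bound peaks on H3K4me3 and with less loss away from it. A hypothesis is that H3K27ac at promoters with RUNX1 may depend more on BRG1 where BRG1 is also bound. It was not tested, and it does not address the lower loss with BRG1 away from H3K4me3. Among DMSO peaks with RUNX1, the difference between these 2 effects was 21.6 points. Within 10 bins of peak width it was 10.1 points (7.25 to 12.8). Width as binned may account for part of the difference but not all, and width differences within a bin stay open. Counting ACBI peaks within 1 kb of the DMSO peak as present gave 9.50 points (6.71 to 12.1). This argues against peaks shifted by the caller as the whole cause. It cannot test splitting, since a DMSO peak that is split in ACBI is still overlapped and counts as kept. Counting at RUNX1 peaks gave 23.9 points without adjustment and 21.0 points (17.8 to 24.0) in bins of RUNX1 width. That width is a stand-in for stronger binding and leaves H3K27ac width unadjusted. The values show that RUNX1 peak width as binned accounted for little of the difference. They cannot decide on stronger RUNX1 binding, which stays open, since the H3K27ac width was left unadjusted. The 1 kb rule was not applied at RUNX1 peaks, so gaps in split H3K27ac peaks stay open there. Seen from the H3K4me3 peaks in DMSO H3K27ac, BRG1 went with a crude difference in share lost of -1.07 points and one of 5.09 points (3.26 to 6.94) at the same H3K4me3 widths, which was 7.29 (5.29 to 9.33; crude 3.52) with RUNX1 and 2.92 (-0.50 to 6.44; crude -3.60) without it, so more loss with BRG1 was not shown at promoters without RUNX1, while BRG1 peaks on H3K4me3 kept H3K27ac in 74.2% of cases with RUNX1 and 75.6% without it (intervals 72.7 to 75.6 and 72.5 to 78.5), which does not set these apart. The height of the H3K27ac signal, which no list gives, and the depth of the ACBI library stay open, as does whether BRG1 binding was lost at these sites.

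The third pattern is that chromosome 20 kept more H3K27ac covered length, relative to DMSO, than the other autosomes and X, although by share of peaks lost chromosomes 22 (49.4%) and 19 (49.5%) were lower. It was picked because its bins had the highest median log2 ratio of these chromosomes, -0.50 over 13 bins against -0.93 over all bins, so that value is no test of the pattern. The values argue against its make-up by peak width and H3K4me3 as the cause: 49.7% of its DMSO peaks were lost (47.9 to 51.6) where the other chromosomes gave 58.6% for the same make-up, a difference of -8.90 points (-10.8 to -7.04). That interval covers counting error only and takes neighbouring peaks as independent. For the other autosomes and X, the same difference ran from -4.69 points on chromosome 22 to 3.99 points on chromosome 8. Chromosome 20 was picked from the same H3K27ac lists, so its difference is not an independent test. Without its 3 highest bins the median was -0.69 (-0.87 to -0.49), against -0.93 over all bins. That leaves a few long domains open. A median already resists a few high bins, and these same bins were used to pick the chromosome. A different copy number of chromosome 20 in the cells of the 2 libraries, and GC content, could not be examined without reads or sequence and stay open, and no biological explanation was tested.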
